A study of Zea mays with 36 samples.

How the data were processed

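RNA of the shoot apical meristem, the dome of dividing cells at the tip of a seedling, was compared between rgd2-R mutant and non-mutant maize. Per the labels' protocols, the mutation had been introgressed into the inbred line Mo17 for 5 generations, and both genotypes grew under one controlled condition until 14 days after germination. Meristem cells were then collected by laser microdissection, and their RNA was extracted and amplified in 2 rounds. Amplified RNA was labelled with Cy3 or Cy5 through amino allyl nucleotides, and the dyes were swapped between replicates. Each hybridisation held both genotypes, and 2 spotted array designs named SAM1 (19200 spots) and SAM3 (16000 spots) were used. Each design carried 6 biological replicates, with rgd2-R in Cy3 in replicates 1 to 3 and in Cy5 in replicates 4 to 6. Each replicate was represented by 3 readings named low, mid and high, so that 36 samples stand for 12 hybridised replicates.

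The deposited intensity values are scanner signal and local background per spot and dye, not corrected and not normalized, per the file headers. The deposited files also hold a processed natural log ratio for each reading. Its method of background correction and normalization is not given in the sources used here. The base was read from the slope of the per-dye processed values against the natural log of background-subtracted signal, with a median of 0.96 and a range of 0.801 to 1.26. In the authors' value table the columns run as non-mutant over rgd2-R in all replicates, by the dyes in the labels, with column medians of -0.08 to 0.04. The name and settings of the authors' image software are not given in the sources used here.

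All ratios below are log2 of rgd2-R over non-mutant. Mean signal and mean background were corrected with normexp (offset 50) and normalized by loess within each array, in limma 3.58.1 under R 4.3.3. The 3 readings of a replicate were averaged, which leaves 6 values per spot and array. A linear model with a dye term and a genotype term, which leaves 4 residual degrees of freedom, was fitted with lmFit and eBayes. Spots were called at a Benjamini-Hochberg adjusted p under 0.05. The arrays carry different probes and were fitted apart. No source used here marks control spots, so no spot was left out. Standard errors are those of the limma model and SDs are over the 6 replicates. All p-values are two-sided.

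Gene names came from the platform annotation, updated through current gene identifiers. On SAM1, 1800 probes had 1 gene, 23 had several and 17377 had no name here. On SAM3 these numbers were 1159, 1 and 14840. Named probes stood for 583 genes on SAM1, of which 562 were in the current gene table, and for 598 genes on SAM3, of which 580 were. A probe with several genes was given no name. No genome coordinates are given because no sequence or genome was used here.

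The genes named in the text follow a rule fixed before the data were examined. Per array it takes up to 8 named probes in each direction that pass the threshold with the same sign in all 6 replicates, filled up with the smallest unadjusted p and 1 probe per gene. It adds probes of ragged seedling2, argonaute genes, leafbladeless1 and auxin response factors, and up to 4 members per gene list with the smallest p over both arrays. The 16 gene lists were fixed at the same time. They cover the small RNA pathway, auxin response, KNOX and meristem homeobox genes, leaf polarity, cytokinin and gibberellin, cell cycle and DNA replication, histones, ribosomal proteins, photosynthesis, cell wall, epidermis and cuticle, vascular and lignin genes, heat shock and chaperones, stress and defence, transposable elements, and chromatin. The photosynthesis, epidermis and vascular lists stand for other cell types that a captured apex could hold. Membership came from symbol and word patterns matched to gene symbols and synonyms, not to gene descriptions. A gene can therefore belong to more than 1 list or be missed, as abp1 was by the auxin list. A few matches judged to be of another class, such as arf1 in the auxin list, were taken out by hand before expression values were seen. A short or empty list is therefore no count of such genes on an array. Kinesin genes such as kin4 and krp13 are in the cell cycle list, most of them through symbols of the form krp. Probes of one gene were averaged, and lists with at least 5 genes on an array were tested with camera at a preset inter-gene correlation of 0.01. A gene's adjusted p over all genes tested covers these averaged genes and every other spot, each spot without a single gene name kept as its own row. That gave 9 lists on SAM1 and 10 on SAM3, adjusted within an array. Estimated correlations and fry were run beside it. Smaller lists are described by value.

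The model was tested on simulated data with the residual SDs of each array and 200 changed probes among all of its probes. For SAM1, 93% of probes changed 2-fold and 100% of those changed 4-fold were recovered, with 10 false calls. For SAM3, the shares were 86% and 98%, with 12 false calls. Simulated 2-fold changes on SAM3 came back at 0.99 of their true size. The simulated replicates ran in their labelled direction, so this is no check of the labels. The SAM3 shares do not apply where readings or replicates ran opposite to their labels, which is in doubt for replicates 2 and 3. The number of replicates limits the precision of each ratio. The median signal was 1.48 to 3.79 times the median background in Cy3 and 3.25 to 6.38 times in Cy5 on SAM1. On SAM3 these ranges were 2.10 to 9.57 and 2.39 to 13.0, or 2.10 to 6.05 and 3.32 to 13.0 without the low and mid readings of replicate 3. Between 3.56% and 12.2% of spots per reading and dye did not exceed their background.

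Alternatives fixed beforehand covered background correction, loess, scaling between arrays, each reading alone, the median of readings, the dye term, separate channels without the hybridisation as a block, a filter on dim probes, saturated readings, the variance model, array weights, the authors' value table, each replicate left out, the threshold, and the set test. Chosen after seeing the data were 3 settings for SAM3 replicates 2 and 3 and a set test against named genes alone. Correlations between readings of a replicate used only spots more than 100 units above background in both dyes of the first-named reading. Their log ratios were the deposited processed ones. In SAM3 replicate 3 the low and mid readings ran opposite to the high reading, with correlations over spots of -0.923 and -0.906. The SAM3 replicates with rgd2-R in Cy3 also disagreed as labelled, with a correlation of -0.544 between replicates 1 and 3. With those 2 readings exchanged it became 0.62. Replicate 2 then still ran opposite, at -0.242 with replicate 1 and -0.343 with replicate 3. The direction of SAM3 ratios is therefore not settled. SAM3 values are given with the dyes as labelled, and the ratios of named probes, named genes and lists also with the channels of those 2 readings exchanged and with replicate 2 turned as well. Standard errors, counts of genes on a side of 0 and ranges with a replicate left out are as labelled. As labelled, replicate 3 averages readings that run opposite to each other and partly cancel. The median residual SD of SAM3 was then 0.192, against 0.24 with the exchange. SAM3 standard errors, list p-values and counts as labelled therefore rest on a partly cancelled replicate.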

Results

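The series asks how the transcriptome of the shoot apical meristem differs between rgd2-R and non-mutant maize seedlings. ragged seedling2 encodes an ARGONAUTE7-like protein of the small RNA pathway, and its mutants form narrow leaves. Meristem cells microdissected at 14 days after germination gave 6 biological replicates on each of the SAM1 and SAM3 arrays, each replicate being a hybridisation of rgd2-R against non-mutant RNA read 3 times. Readings of one replicate correlated at 0.412 to 0.891 over brighter spots in 34 of 36 pairs. These values are from the deposited processed ratios of 3407 to 13303 spots more than 100 units above background, so they do not cover dim spots. The other 2 pairs, both in SAM3 replicate 3, were negative at -0.923 and -0.906. No probe was named here as rgd2 or another argonaute gene, so the mutated gene itself is not analysed here and gives no check of the labels. No probe was taken as an auxin response factor either. The name arf1 was left out because it may stand for an ADP-ribosylation factor, and its identity was not settled.

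**Figure D1:**
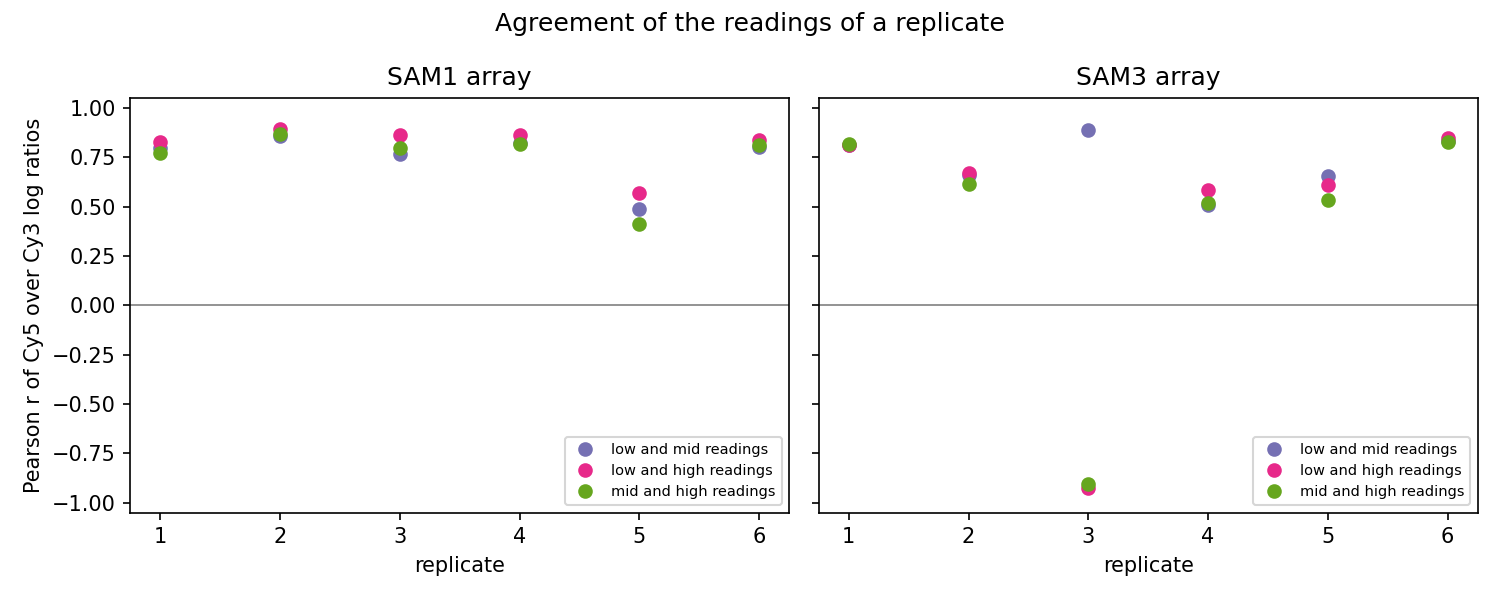
Correlation over spots of the deposited processed log ratios of 2 readings of the same replicate, by array and replicate, for the low and mid, low and high, and mid and high readings. Only spots more than 100 units above background in both dyes of the first-named reading are used. In SAM3 replicate 3 the high reading correlates at -0.923 and -0.906 with the low and mid readings, while the lowest value elsewhere is 0.412 in SAM1 replicate 5.

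On SAM1 the single named probes with the smallest p-values were of apx2, an ascorbate peroxidase, and ccp1, a cysteine protease. A probe of apx2 was higher in rgd2-R with a log2 ratio of 0.45 (SE 0.05, 1.37-fold), in 6 of 6 replicates. A probe of ccp1 was lower with a log2 ratio of -0.72 (SE 0.08), in 6 of 6 replicates. Both had a limma adjusted p of 0.0921 and did not pass the threshold. OBF1, a bZIP factor that binds ocs elements, gave -0.75 (SE 0.12), grp1 gave -0.95 (SE 0.14) and cys2 gave -0.45 (SE 0.09), each lower in 6 of 6 replicates. RR9, a cytokinin response regulator, gave -0.39 (SE 0.07) and was also lower in 6 of 6. The auxin-binding protein gene abp1 gave -0.41 (SE 0.08) and trxh1, a thioredoxin h, gave -0.48 (SE 0.09), each lower in 5 of 6 replicates. IDP3803 gave -0.59 (SE 0.10) and was lower in 4 of 6. Its values were -1.524 to -0.936 with rgd2-R in Cy3 and -0.255 to 0.337 with rgd2-R in Cy5. Among probes with higher values, hsp70-5, an HSP70 chaperone, gave 0.37 (SE 0.08), PPP2R5B gave 0.32 (SE 0.07), nfd106 gave 0.29 (SE 0.06), CaM1, a calmodulin, gave 0.29 (SE 0.06) and GP gave 0.26 (SE 0.05), each in 6 of 6 replicates. lim1 gave 0.33 (SE 0.05) with 4 of 6 replicates higher, and EF1A, a translation elongation factor, gave 0.24 (SE 0.05) with 3 of 6 higher. With rgd2-R in Cy3, lim1 was 0.561 to 0.736 and EF1A 0.452 to 0.505. With rgd2-R in Cy5 they were -0.069 to 0.075 and -0.03 to -0.001. The dye term takes up a difference between orientations, so the standard errors do not contain it.

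Other probes of several of these genes did not share the value of the named probe. The 3 ccp1 probes ran from -0.72 to 0.13, the 4 OBF1 probes from -0.75 to 0.23, the 28 grp1 probes from -0.95 to 0.33 and the 5 apx2 probes from -0.01 to 0.45. The 2 PPP2R5B probes gave 0.32 and -0.15, the 2 IDP3803 probes -0.59 and -0.02, the 4 abp1 probes -0.41 to 0.13, the 4 cys2 probes -0.45 to 0.04, the 7 lim1 probes -0.08 to 0.56 and the 24 EF1A probes -0.08 to 0.90, with 8 below 0. By contrast, all 8 probes of hsp70-5 (0.16 to 0.46), all 9 of nfd106 (0.14 to 0.34) and all 11 of CaM1 (0.05 to 0.29) were above 0, and all 6 of trxh1 (-0.48 to -0.02) were below 0. RR9 had 1 probe. Averaged over the probes of a gene, RR9 had the smallest limma p of the named SAM1 genes (unadjusted p = 0.000752), followed by IDP3803 (0.00136) and hsp70-5 (0.00138), while ccp1 gave -0.19 (SE 0.06, unadjusted p = 0.00951) and apx2 0.15 (SE 0.05, unadjusted p = 0.0148).

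Over all 19200 SAM1 probes, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.0921. At an unadjusted p under 0.05 there were 2842 probes, 1283 higher and 1559 lower, where 960 are expected by chance. The 9 probes under an adjusted p of 0.10 were 2 higher and 7 lower, of which 7 had no gene name here. In 6.9% of probes all 6 replicates had the same sign, against 3.125% by chance. Averaged by gene, 36 named genes were higher and 34 lower at an unadjusted p under 0.05, and the smallest adjusted p over named genes was 0.246. The count of 0 depended on the processing. Without background correction 195 probes passed, 53 higher and 142 lower, among them probes of apx2, ccp1, grp1, OBF1 and IDP3803. With the dimmest 25% of probes left out 42 passed, 7 higher and 35 lower, among them apx2, ccp1, grp1 and OBF1.

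**Figure D2:**
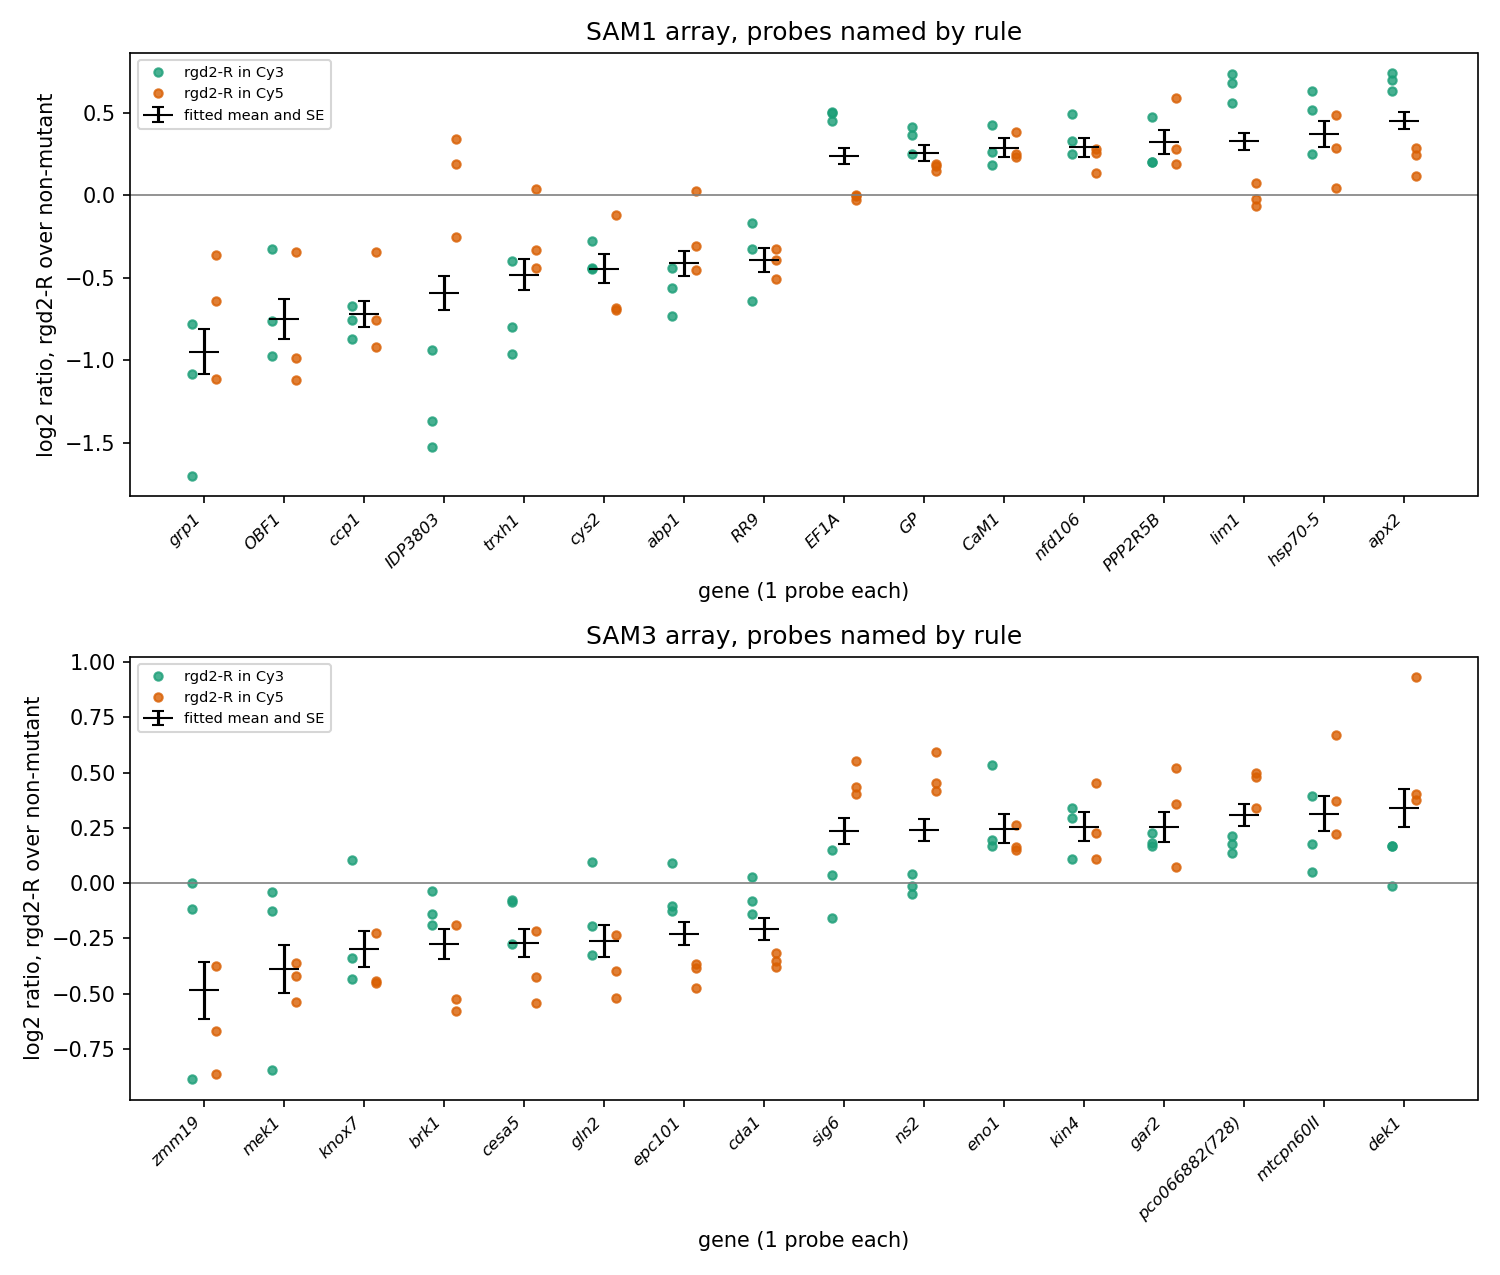
Log2 ratio of rgd2-R over non-mutant for the probes named by rule on SAM1 and SAM3, with points for the 6 replicates, coloured by the dye of rgd2-R, and the mean with its standard error. The ccp1 and apx2 probes lie on the same side of 0 in all 6 SAM1 replicates, at means of -0.72 and 0.45, and no probe shown passes the adjusted threshold of 0.05.

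The mean of the KNOX and meristem homeobox list on SAM1 depended on replicate 3, where rs2 (1.55), ns2 (1.87), yab9 (1.85), yab10 (1.55) and yab14 (1.45) were high and kn1 (-0.21), knox7 (0.03) and wox13B (-0.03) were not. Of its 9 members, 7 were above 0 and 2 below, with a mean of 0.20, or 0.05 without replicate 3. lg3, a KNOX gene, gave 0.17 (SE 0.06) and was higher in 6 of 6 replicates. rs2, a MYB gene that represses KNOX genes, gave 0.49 (SE 0.20) and was higher in 5 of 6, at 0.26 without replicate 3. kn1, the KNOX gene that marks meristem cells, gave -0.12 (SE 0.08). The list did not pass (camera adjusted p = 0.264), and its mean in replicate 3 was 0.94 while the other 5 replicates lay between -0.07 and 0.22. Of the 4 leaf polarity genes, too few to test, all were above 0, with yab9 at 0.40 (SE 0.25) and yab10 at 0.32 (SE 0.20). Without replicate 3 they were 0.09 and 0.08, and the mean of the 4 genes over the other 5 replicates was -0.004. The YABBY genes yab9, yab10 and yab14 are counted in both lists. With a replicate left out the mean of the KNOX list ran from 0.05 (without replicate 3, camera adjusted p = 0.441) to 0.30 (without replicate 2, camera adjusted p = 0.0369). Only the latter passed, where fry gave an adjusted p of 0.476. With all 6 replicates the camera adjusted p of the list was 0.653 with an estimated correlation.

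Of the 6 cytokinin and gibberellin genes of SAM1, 4 were below 0, among them RR9 at -0.39 and an1, an early gibberellin synthesis gene, at -0.13 (SE 0.06). RR9 passed when adjusted over the list alone (limma adjusted p = 0.00451), not over all genes tested, unnamed spots included (adjusted p = 0.102), or over named genes alone (adjusted p = 0.246). The list itself did not pass (camera adjusted p = 0.264, mean -0.09, median -0.04). The auxin response list held 1 gene, BA1, at -0.04 (SE 0.07). The small RNA pathway list held 1 gene, lbl1, an SGS3-like gene of the trans-acting small RNA pathway in which ARGONAUTE7 acts. Its 4 probes gave -0.10, -0.24, -0.23 and -0.18, with a mean of -0.18 (SE 0.08), lower in 4 of 6 replicates. For lbl1 the p was 0.045 adjusted over the list alone, a list of 1 gene, and 0.339 over all genes tested.

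Growth genes on SAM1 did not pass as groups, except that with each probe counted on its own the ribosomal list (mean 0.10) and the chromatin list (mean 0.08, camera adjusted p = 0.0443) passed. That setting counts probes of 1 gene as separate members, and there fry gave adjusted p-values of 0.206 (ribosomal) and 0.306 (chromatin). With an estimated correlation over genes both were at 0.653. In the cell cycle and DNA replication list 7 of 10 genes were above 0 (camera adjusted p = 0.264), with pcna1, a DNA polymerase clamp, at 0.22 (SE 0.09) and kin4, a kinesin gene in the list through its alias krp4, at 0.27 (SE 0.09). Among the 15 ribosomal protein genes 11 were above 0 (camera adjusted p = 0.264). RPL10 gave 0.27 (SE 0.07), RPL27A 0.22 (SE 0.07) and rpp2 0.22 (SE 0.08), while rps21b gave -0.87 (SE 0.27). The ribosomal list's mean of -0.003 and its median and test, which are positive, differ in sign for that reason. The chromatin list had 6 of 9 genes above 0 (camera adjusted p = 0.582), with the deacetylase gene hda106 at 0.21 (SE 0.11), or 0.08 with 1 of the replicates left out, met2 at 0.16 (SE 0.07), dmt101 at 0.10 (SE 0.05) and SDG123 at -0.15 (SE 0.06). The 4 histone genes had a mean of 0.08, with cenH3 at 0.16 (SE 0.14), his2b5 at 0.11 (SE 0.08) and his1 at 0.08 (SE 0.05), and with a replicate left out cenH3 went down to 0.01 and his2b5 to 0.02. In the cell wall list 3 of 10 genes were above 0 (camera adjusted p = 0.807), with prp2 at 0.37 (SE 0.13), the cellulose synthase genes cesa2 at 0.15 (SE 0.06) and cesa3 at -0.17 (SE 0.07), and a mean above 0 beside a median and a test below it.

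All 4 heat shock and chaperone genes of SAM1 were above 0, with a mean of 0.19. hsp70-5, averaged over its 8 probes, gave 0.38 (SE 0.08) and hsp22 gave 0.14 (SE 0.07), each higher in 6 of 6 replicates. hsp70-5 passed when adjusted over the list alone (limma adjusted p = 0.00552), not over all genes tested (adjusted p = 0.12) or over named genes alone (adjusted p = 0.246). The list was too short to test. The stress and defence list had 16 of 25 genes above 0 with a mean of 0.007 (camera adjusted p = 0.779), apx2 giving 0.15 (SE 0.05) over its 5 probes, gst28 0.17 (SE 0.09), chn1 0.14 (SE 0.07) and the dehydrin gene dhn2 -0.14 (SE 0.06). Markers of other cell types did not pass either. The photosynthesis list had 8 of 10 genes above 0 (mean 0.03, camera adjusted p = 0.585), with mdh6 at -0.13 (SE 0.06) and psan1 at 0.08 (SE 0.05). The vascular and lignin list had 4 of 5 below 0 (mean -0.05, camera adjusted p = 0.585), with sh1 at -0.12 (SE 0.11) and ss2 at -0.09 (SE 0.09), each -0.01 with 1 of the replicates left out. Of the 4 epidermis genes, ocl4, an outer cell layer homeobox gene, gave 0.21 (SE 0.06) in 6 of 6 replicates, passing when adjusted over the list alone (adjusted p = 0.0364) and not over all genes tested (adjusted p = 0.186). ocl2 gave 0.03 (SE 0.05). With an estimated correlation, the smallest adjusted p of a SAM1 list was 0.653. The transposable element list held 0 named genes on SAM1 and on SAM3.

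**Figure D3:**
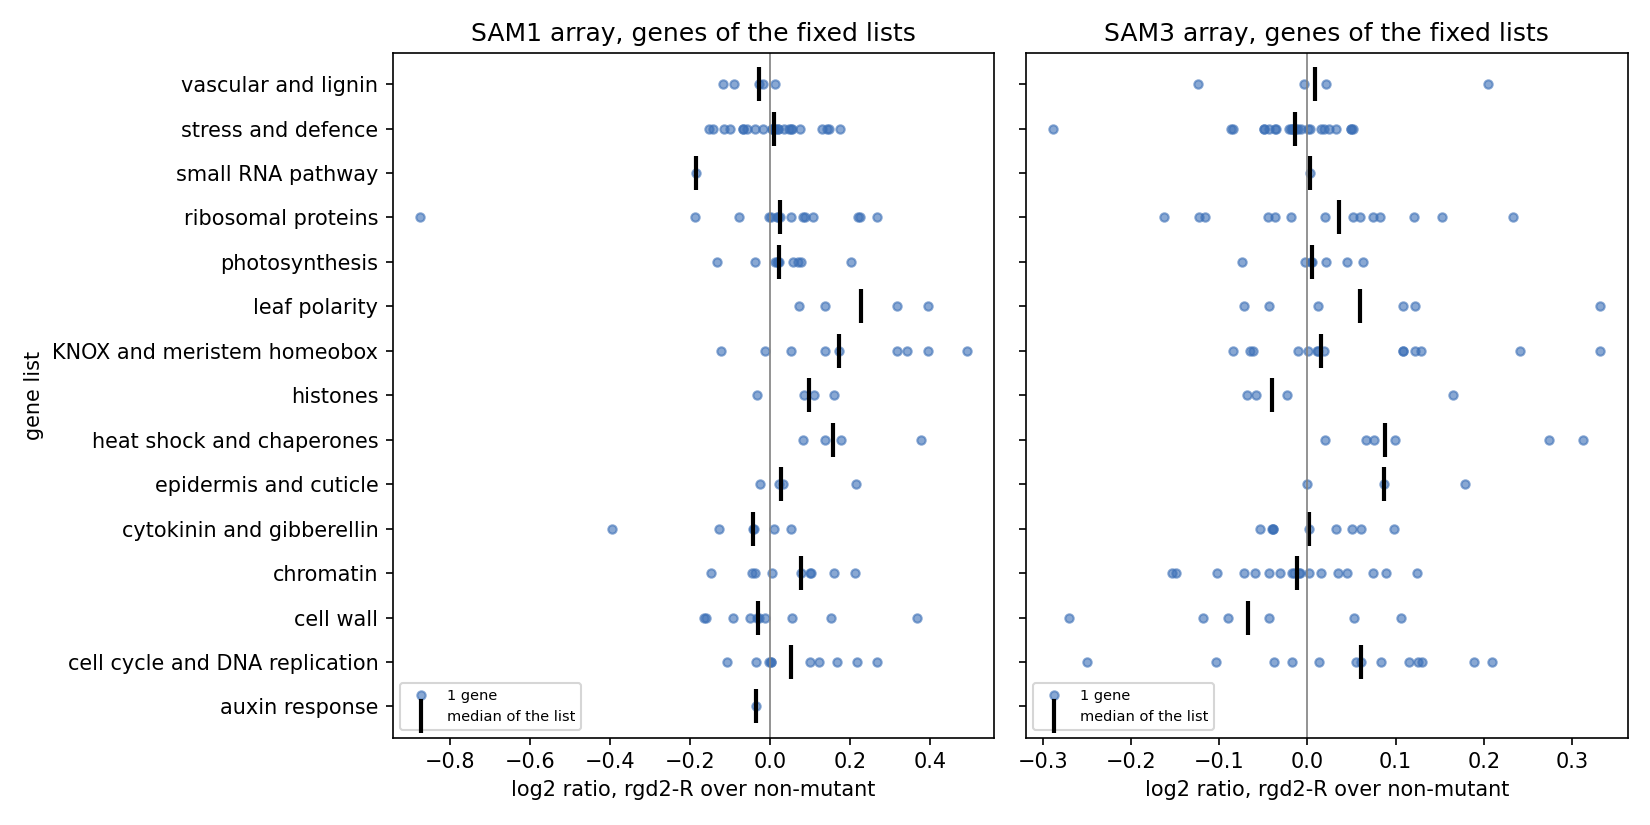
Log2 ratio of rgd2-R over non-mutant for each measured gene of the fixed lists on SAM1 and SAM3, with dyes as labelled and the median of each list. The x ranges of the panels differ. The heat shock and chaperone genes all lie above 0, with means of 0.19 on SAM1 and 0.14 on SAM3, and the SAM1 ribosomal gene at -0.87 is rps21b.

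On SAM3 the probe with the largest ratio among those named was zmm19, a MADS box gene, at -0.48 (SE 0.13), lower in 5 of 6 replicates with the dyes as labelled. mek1, a MAP kinase kinase, gave -0.39 (SE 0.11), knox7 -0.30 (SE 0.08), brk1, needed for lobes of epidermal cells, -0.28 (SE 0.07), the cellulose synthase gene cesa5 -0.27 (SE 0.06), gln2 -0.26 (SE 0.07), epc101 -0.23 (SE 0.05) and cda1 -0.21 (SE 0.05). Higher values were given by dek1, a calpain of epidermal fate, at 0.34 (SE 0.09), by mtcpn60II, a mitochondrial chaperonin, at 0.31 (SE 0.08), and by a gene with only a clone name here at 0.31 (SE 0.05). gar2 and kin4 both gave 0.26 (SE 0.07), the enolase gene eno1 0.25 (SE 0.06), ns2, a WOX gene for the margins of the leaf, 0.24 (SE 0.05) and sig6, a plastid sigma factor, 0.24 (SE 0.06). The smallest adjusted p among these 16 probes was 0.552, so none of them passed in limma. Other probes of these genes often lay nearer 0 or across it, and the 4 knox7 probes ran from -0.30 to 0.05, the 2 epc101 probes from -0.23 to 0.15, the 2 sig6 probes from -0.08 to 0.24, the 4 kin4 probes from -0.05 to 0.26, the 2 mek1 probes from -0.39 to -0.04 and the 4 eno1 probes from 0.04 to 0.25. All 3 probes of zmm19 (-0.48 to -0.15), cesa5 (-0.36 to -0.18) and cda1 (-0.21 to -0.07) were below 0, and both of dek1 (0.17 to 0.34) and mtcpn60II (0.31 and 0.31) above it. With the 2 readings of replicate 3 exchanged all 16 kept their sign, with zmm19 at -0.59, mek1 at -0.35, dek1 at 0.32 and ns2 at 0.28, but knox7 at -0.08, gln2 at -0.04 and kin4 at 0.06. The others were then brk1 -0.16, cesa5 -0.15, epc101 -0.16, cda1 -0.11, mtcpn60II 0.22, the gene with a clone name 0.18, gar2 0.09, eno1 0.16 and sig6 0.26. With replicate 2 turned as well, knox7 (0.03), gln2 (0.03), kin4 (-0.05) and eno1 (-0.02) took the other sign, while zmm19 (-0.55), mek1 (-0.31), sig6 (0.32), ns2 (0.28) and dek1 (0.26) did not. Values of brk1 (-0.14), cesa5 (-0.12), epc101 (-0.19), cda1 (-0.06), mtcpn60II (0.09), the gene with a clone name (0.12) and gar2 (0.03) also kept their sign.

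Over all 16000 SAM3 probes limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.474. At an unadjusted p under 0.05 there were 1053 probes, 479 higher and 574 lower, where 800 are expected by chance. As labelled, 3.2% of probes had the same sign in all 6 replicates, against 3.125% by chance. Replicate 3 averages opposite readings there, so the share cannot tell whether the replicates agree. It is not given for the other directions. With the 2 readings exchanged the call stayed at 0, with 1185 probes at an unadjusted p under 0.05, 419 higher and 766 lower. With replicate 2 turned as well 2 probes without a gene name here passed, at log2 ratios of -1.20 (SE 0.09) and 1.17 (SE 0.08), and 2664 had an unadjusted p under 0.05. Replicate 2 was turned because it ran opposite to replicates 1 and 3 in these same data. That choice by itself can raise the counts in this setting, so the rise is no evidence for the turn or for an effect. Among named genes, 20 were higher and 14 lower at an unadjusted p under 0.05 with the dyes as labelled, 10 higher and 24 lower with the exchange, and 39 higher and 53 lower with replicate 2 turned as well, so the direction of these counts is not settled.

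The heat shock and chaperone list was the 1 list that passed on SAM3 with the dyes as labelled (camera adjusted p = 0.00606). Its mean was 0.14, with 6 of 6 genes above 0 as labelled, a count not given for the other directions. The list means of replicates 1 to 3, with rgd2-R in Cy3, were -0.105, -0.025 and 0.096. Those of replicates 4 to 6, with rgd2-R in Cy5, were 0.264, 0.218 and 0.401. The list's adjusted p was 0.246 with an estimated correlation and 0.173 with fry. At the preset correlation the camera adjusted p was 0.177 with plain background subtraction, 0.549 from the high reading alone and 0.264 from the authors' value table. The call therefore depended on the preset correlation and on the processing. CPNA and mtcpn60II, both mitochondrial chaperonin 60 genes, gave 0.27 (SE 0.07) and 0.31 (SE 0.08), each at an adjusted p of 0.017 adjusted over the list alone and 0.568 over all genes tested. Exchanged, CPNA was 0.27 and mtcpn60II 0.20, and with replicate 2 turned as well 0.19 and 0.11. The list mean was 0.05 with an adjusted p of 0.402 when the 2 readings of replicate 3 were exchanged, and was 0.06 with an adjusted p of 0.535 with replicate 2 turned as well. Without replicate 3 the adjusted p was 0.179 and the mean 0.11.

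Meristem and polarity genes on SAM3 did not pass as lists. With the dyes as labelled, 10 of 14 genes of the KNOX and meristem homeobox list were above 0 (mean 0.06, camera adjusted p = 0.157). The list also holds the MYB gene rs2 and the YABBY genes yab9, yab10, yab14 and yabby15. Its KNOX genes kn1, knox3, knox7, knox8 and lg3 lay between -0.065 and 0.019 as labelled, so the count is no shift of KNOX genes. Counts above 0 are not given for the other directions. ns2 gave 0.24 (SE 0.05) and passed when adjusted over the list alone (adjusted p = 0.0284), not over all genes tested (adjusted p = 0.544). Its values with the dyes as labelled lay between -0.05 and 0.04 in replicates 1 to 3 and between 0.42 and 0.59 in replicates 4 to 6. rs2 gave 0.13 (SE 0.06), 0.19 with the 2 readings exchanged and 0.26 with replicate 2 turned as well. The list mean was 0.03 with the exchange and -0.0051 with replicate 2 turned as well. With a replicate left out the mean as labelled ran from 0.04 to 0.09, and without replicate 5, at 0.09, the list passed (camera adjusted p = 0.0416, fry adjusted p = 0.0262). With all 6 replicates the adjusted p was 0.421 with an estimated correlation and 0.302 with fry. In the leaf polarity list 4 of 6 genes were above 0 as labelled (mean 0.08, camera adjusted p = 0.563). yab14 gave 0.33 (SE 0.17) and yab9 0.11 (SE 0.10). Exchanged, the list mean was 0.12, yab14 0.32 and yab9 0.02, and with replicate 2 turned as well they were 0.09, 0.07 and 0.08. As labelled, leaving out a replicate took the list mean from 0.02 to 0.15 and yab14 from 0.16 to 0.44. lbl1 gave 0.003 (SE 0.13) as labelled, from probes at 0.13 and -0.12, -0.18 with the exchange and -0.34 with replicate 2 turned as well.

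Growth, wall and chromatin genes on SAM3 did not pass either, in any of the 3 directions, except that as labelled, with each probe counted on its own, the cell cycle list (mean 0.07, camera adjusted p = 0.0246) and the cell wall list (mean -0.11, camera adjusted p = 0.0196) passed. In that setting fry gave adjusted p-values of 0.257 (cell cycle) and 0.846 (cell wall), and with an estimated correlation over genes they were 0.519 and 0.671. Counts of genes above or below 0 in these lists are as labelled. They are not given for the other directions, so the side on which most genes lay is not settled. In the cell cycle and DNA replication list 9 of 13 genes were above 0 (mean 0.04, camera adjusted p = 0.247), with pcna2 at 0.19 (SE 0.06) and the retinoblastoma-related gene rrb2 at -0.25 (SE 0.09), and the mean was 0.06 exchanged and 0.09 with replicate 2 turned as well. In these 2 settings pcna2 was 0.04 and -0.009, and rrb2 -0.16 and -0.003. In the cell wall list 4 of 6 genes were below 0 (mean -0.06, camera adjusted p = 0.403), cesa5 giving -0.27 (SE 0.08) over its 3 probes, and the mean was -0.09 exchanged and -0.12 with replicate 2 turned as well, with cesa5 at -0.18 and -0.10. With a replicate left out the mean as labelled ran from -0.01 (without replicate 6) to -0.11 (without replicate 4), and only the latter passed (camera adjusted p = 0.0347, fry adjusted p = 0.124). Ribosomal protein genes had 8 of 14 above 0 (mean 0.02, camera adjusted p = 0.403), with means of -0.01 exchanged and -0.04 with replicate 2 turned as well. The cytokinin and gibberellin list had 5 of 9 above 0 (mean 0.008, camera adjusted p = 0.694), with RR8 at 0.10 (SE 0.08) and RR9 at 0.06 (SE 0.06), and means of 0.10 exchanged and 0.12 with replicate 2 turned as well, where RR8 was 0.14 and 0.11. The chromatin list had 11 of 18 below 0 (mean -0.02, camera adjusted p = 0.901), with means of -0.05 exchanged and -0.02 with replicate 2 turned as well.

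Of the 24 stress and defence genes on SAM3, 15 were below 0 as labelled (mean -0.02, camera adjusted p = 0.694). The mean was -0.09 exchanged and -0.10 with replicate 2 turned as well. Counts of stress and photosynthesis genes on a side of 0 are as labelled and are not given for the other directions. The photosynthesis list had 5 of 7 genes above 0 (mean 0.009, camera adjusted p = 0.724), with me3 at -0.07 (SE 0.06) and psbs1 at 0.06 (SE 0.05), and means of 0.02 exchanged and 0.03 with replicate 2 turned as well, where me3 was -0.18 and -0.20 and psbs1 0.04 and -0.01. In lists too short to test, the histone mean was 0.004, with his1 at 0.16 (SE 0.06), the epidermis mean was 0.09, with gl8 at 0.18 (SE 0.11) and ocl1 at 0.09 (SE 0.12), and the vascular mean was 0.02, with ccr2 at 0.21 (SE 0.14) and ss2 at -0.12 (SE 0.10). With the exchange the histone, epidermis and vascular means were -0.11, -0.02 and -0.14, and with replicate 2 turned as well -0.14, -0.15 and -0.17. With the exchange his1 was 0.05, gl8 0.09, ocl1 -0.08, ccr2 -0.18 and ss2 -0.24. With replicate 2 turned as well they were 0.08, -0.13, -0.21, -0.34 and -0.23. The auxin response list held 0 genes on SAM3.

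Of the genes named on either array, 415 were on both. Across these genes the log2 ratios of SAM1 and SAM3 correlated at a Pearson r of 0.312 and a Spearman rho of 0.285, and 58.3% had the same sign. Genes are not independent replicates, and no p is given. The labels do not say whether the same RNA was put on both arrays, and shared samples would correlate without an effect of the genotype, so these values are no evidence of one. With the 2 readings of SAM3 replicate 3 exchanged r was 0.242 and 55.4% had the same sign, and with replicate 2 turned as well r was 0.321 and 55.7%. rs2 gave 0.49 (SE 0.20) on SAM1, or 0.26 without replicate 3, and ns2 gave 0.34 (SE 0.24), with 1.87 in replicate 3, between -0.07 and 0.28 in the other replicates, and 3 of 6 above 0. RR9, at -0.39 on SAM1, gave 0.06 (SE 0.06) on SAM3 as labelled, 0.02 exchanged and -0.03 with replicate 2 turned as well, from a probe at intensity percentile 86.4 on SAM1 and 11.3 on SAM3, so the SAM3 value is from a dim spot and the pair is no comparison of the gene. hsp70-5, at 0.38 on SAM1, gave 0.07 (SE 0.11) on SAM3 from 1 probe, above 0 in 4 of 6 replicates. lg3, at 0.17 on SAM1, gave 0.001 (SE 0.10) on SAM3, above 0 in 3 of 6. Both SAM3 values are given as labelled only. trxh1 and nfd106, described under other observations, had the same sign on both arrays as labelled. The difference between arrays was not tested for any gene.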

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

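The tests of SAM3 replicate 3 by its background, those of the leaf polarity genes, the pairing of replicates between arrays and the counts over other splits of the replicates were chosen after the results were seen; the test of SAM3 replicate 2 and a first test of SAM3 replicate 3, both by correlation with SAM1, were written before. Of 122 results with 6 replicates, 8 had 1 replicate whose gap to the nearest other exceeded Dixon's critical value for 6 values, where chance gives 6.1. They were the KNOX list and hda106 on SAM1, eno1 on SAM3, and reading correlations of SAM1 replicate 5 and SAM3 replicate 3. Reading correlations were most of them, so the comparison with chance holds for neither kind alone. The leaf polarity list did not exceed the critical value.

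In SAM3 replicate 3 the high reading ran opposite to the others, at -0.923 with the low and -0.906 with the mid reading, while the other 5 replicates gave 0.517 to 0.847. The correlations with SAM1 replicate 3 (-0.08 low, -0.086 mid, 0.104 high) left the cause undecided. Channel signals of the low and high readings correlated at 0.681 in the same columns and 0.964 in crossed columns. For the mid and high readings these values were 0.731 and 0.968. In the 34 other pairs of readings the same columns correlated more than the crossed ones. With the low and mid readings exchanged, replicate 3 correlated at 0.62 with SAM3 replicate 1, against -0.544 as labelled. The Cy3 median background was 2.05 to 7.88 times the Cy5 one in the 33 readings of other replicates, but 0.121 and 0.143 times in the low and mid readings, which is consistent with exchanged channel columns in those 2 readings. For the high reading it was 11.3 as deposited and would be 0.088 if exchanged, which argues against an exchange there. A first criterion, that the ratio should lie inside 2.05 to 7.88, had been undecided, with 8.26 for the low and 6.99 for the mid reading after exchange and 11.3 above it for the high reading, so the criterion became above or under 1, and no biological explanation was tested.

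SAM3 replicate 2 correlated at -0.242 with replicate 1 of the same dye orientation, and at -0.343 with replicate 3 once its 2 readings were exchanged, and a candidate explanation is that its dyes ran opposite to the label. Its Cy5 over Cy3 ratios correlated at 0.138 (SE 0.049) with SAM1 replicate 2 over shared genes, where the criterion against a turned dye was above 0.1. That exceeds the criterion by less than its standard error, and same-numbered replicates of the arrays correlated above 0.1 in only 3 of 6 cases, so the explanations cannot be told apart. A pairing of replicate numbers 3 apart, tried after the data were seen, had a mean correlation of rgd2-R over non-mutant ratios of 0.166 (exact permutation p = 0.0264 over 720 pairings, not adjusted for the 2 pairings tried), against 0.101 (exact permutation p = 0.204) for the same number. Under it SAM3 replicate 2 belongs with SAM1 replicate 5, at -0.273, which points the other way from 0.138. SAM3 replicates 1, 4, 5 and 6 then gave 0.228, 0.454, 0.363 and 0.234, and replicate 3 gave -0.012 as labelled. A biological difference between plants was not tested.

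In SAM1 replicate 3 the mean of the KNOX and meristem homeobox list was 0.939, with the others at -0.071 to 0.217, and the leaf polarity mean was 1.40, carried by yab9 (1.85), yab10 (1.55) and yab14 (1.45), beside ns2 (1.87) and rs2 (1.55). An error in 1 reading is argued against, since the lowest of its 3 readings was 1.36 and the highest reading of other replicates 0.407. The leaf polarity mean of the other 5 replicates was -0.004 (SD 0.26). More leaf primordium tissue in the rgd2-R sample of this replicate stays open: kn1, which is expressed outside primordia, was -0.208 there and between -0.341 and 0.308 elsewhere, so it did not decide. The genotype in combination with the plants of this replicate also stays open and was not tested.

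In SAM1 replicate 5 the readings correlated at 0.49 (low and mid), 0.57 (low and high) and 0.412 (mid and high), while the other replicates gave 0.767 to 0.891. hda106 on SAM1 was 0.776 in replicate 1 and between -0.063 and 0.248 in the others. The eno1 probe on SAM3 was 0.534 in replicate 2 and between 0.149 and 0.262 in the others.

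The 6 replicates of an array can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In limma all 10 splits gave 0 probes past the threshold on SAM1, and all 10 did so on SAM3, with a highest other count of 0. At an unadjusted p under 0.05 the dye orientation of SAM1 gave 2842 probes, 1 of 10 splits with as many, and the highest other gave 1250. On SAM3 the orientation gave 1053 probes, while the splits that set replicates 1, 4 and 5 or 1, 5 and 6 against the rest gave 1684 and 1306. With SAM3 replicate 3 exchanged the orientation gave 1185, the split of replicates 1, 3 and 5 gave 2248, and the former 2 splits gave 236 and 216. For lists as labelled, 2 of 10 SAM3 splits gave as many as the orientation's 1 list, the highest other being 1. With replicate 3 exchanged the orientation gave 0 lists and the split of replicates 1, 2 and 5 gave 2. On SAM1 the orientation gave 0 lists and 2 other splits gave 1 each.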

How the results depend on the processing

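Chosen after the data were seen were the 3 settings for SAM3 replicates 2 and 3 and the set test against named genes alone; the other settings were fixed before. Print-tip loess was not run, since no print blocks are in the files used. On SAM1 the limma count of 0 probes became 195 without background correction, 42 with the dimmest 25% of probes left out, 36 from the mid reading alone, 11 with median centring, 1 (unnamed, 1.41) from the authors' value table and 9 at an adjusted p under 0.10, and 0 to 2 with a replicate left out, the 2 without replicate 2. The filter tests fewer probes and also refits eBayes on the probes kept, so the p-values themselves changed as well. The causes of these changes in count were not tested. On SAM3 the count stayed 0 in each setting, 0 to 0 with a replicate left out, but for 2 with replicate 3 exchanged and replicate 2 turned. That turn was chosen from the disagreement of replicate 2 in these data, which by itself can raise the count. Without the hybridisation as a replicate block the counts were 0 and 0 (482 and 189 at an unadjusted p under 0.05), and 1 list passed. Pairing of the arrays by replicate number was not used: same-numbered replicates correlated at -0.056 to 0.351, and 1 of 6 correlated best with its own number. Instead of 1 list, 0 passed with an estimated correlation, plain subtraction, the high reading alone, the authors' value table, fry, and each of the 3 settings of SAM3 replicates 2 and 3, 5 passed with each probe on its own (SAM1 ribosomal proteins and chromatin, SAM3 cell cycle, cell wall and heat shock), and 0 to 2 with a replicate left out. The cause was not tested.

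Some list means and named genes took the other sign, and only 1 of these values passed, SAM1 ribosomal proteins at 0.0965 with each probe on its own. That setting also gave -0.0098 for SAM1 cell wall genes. Without background correction the SAM1 means of cell wall and ribosomal genes were -0.0001 and 0.0128, and psbs1 and lbl1 on SAM3 were -0.011 and -0.016. With plain subtraction the SAM1 means were -0.0225 (cell wall), -0.0546 (chromatin), 0.014 (ribosomal) and -0.0353 (stress), those of SAM3 -0.0503 (cell cycle) and -0.0173 (cytokinin), psan1 -0.851 and chn1 -0.061 on SAM1, and lbl1 -0.009 on SAM3. With median centring they were -0.0265 (SAM1 cell wall), 0.0082 (SAM3 chromatin) and 0.021 (BA1). With the dimmest 25% left out the SAM1 cell wall mean was -0.0102. From the low reading alone the means were -0.0033 (SAM1 stress), 0.0045 (SAM3 chromatin), -0.0574 (SAM3 cytokinin), -0.0065 (SAM3 photosynthesis) and 0.0245 (SAM3 stress), RR9 on SAM3 -0.029, ocl2 -0.03 and dhn2 0.004. From the mid reading they were 0.0036 (SAM1 ribosomal), -0.0071 (SAM3 cytokinin), 0.0095 (SAM3 stress) and 0.055 (me3). From the high reading they were -0.0036 and 0.0079 (SAM1 cell wall and ribosomal), -0.0127 (SAM3 ribosomal), 0.092 (BA1), and on SAM3 -0.003 (pcna2), -0.008 (RR9), -0.065 (ocl1), -0.174 (lbl1) and -0.029 (ccr2). The median of readings gave 0.0039 (SAM1 ribosomal), -0.0406 (SAM3 cytokinin) and -0.0095 (SAM3 photosynthesis), and array weights gave -0.0106 and -0.0008 for the latter pair. The authors' value table gave 0.0164 (SAM1 ribosomal), 0.1812 (SAM3 cell wall), -0.0159 (SAM3 cytokinin), -0.0195 (SAM3 ribosomal) and -0.013 (lbl1 on SAM3). With SAM3 replicate 3 exchanged, or taken from its high reading alone, SAM3 values were -0.0116 and -0.0163 (ribosomal), -0.082 and -0.076 (ocl1), -0.181 and -0.181 (lbl1), -0.177 and -0.143 (ccr2). With replicate 2 turned as well they were -0.0051 (KNOX), -0.0368 (ribosomal), -0.05 (kin4), -0.022 (eno1), 0.029 (knox7), 0.026 (gln2), -0.009 (pcna2), -0.03 (RR9), -0.126 (gl8), -0.207 (ocl1), -0.012 (psbs1), -0.343 (lbl1) and -0.342 (ccr2).

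With a replicate left out the SAM1 ranges that crossed 0 were -0.0188 to 0.0327 (cell wall), -0.0334 to 0.0181 (ribosomal), -0.0091 to 0.0245 (stress), -0.082 to 0.018 (BA1) and -0.001 to 0.053 (ocl2). Those of SAM3 were -0.0195 to 0.0462 (cytokinin), -0.0201 to 0.0245 (photosynthesis), -0.0138 to 0.0575 (ribosomal), -0.0505 to 0.0151 (stress), -0.008 to 0.176 (ocl1) and -0.092 to 0.141 (lbl1). The causes of these sign changes were not tested. Ranges that kept their sign but went under 50% of the value from all replicates were, on SAM1, 0.054 to 0.3017 (KNOX), 0.0119 to 0.0556 (photosynthesis), -0.079 to -0.0196 (vascular), 0.083 to 0.293 (hda106), 0.023 to 0.181 (his2b5), 0.014 to 0.323 (cenH3), 0.092 to 0.655 (yab9), 0.083 to 0.544 (yab10), -0.248 to -0.012 (sh1) and -0.186 to -0.013 (ss2). On SAM3 they were 0.019 to 0.0645 (cell cycle), -0.1067 to -0.0126 (cell wall), -0.028 to -0.0014 (chromatin), 0.0169 to 0.1493 (leaf polarity), 0.045 to 0.167 (RR8), 0.023 to 0.092 (RR9), 0.078 to 0.259 (gl8), 0.16 to 0.442 (yab14), 0.079 to 0.315 (ccr2) and -0.188 to -0.037 (ss2). In all settings fixed before, those with a replicate left out included, 8 of 1087 values of SAM1 genes and 15 of 734 of SAM3 genes took the other sign, as did 24 of 215 values of SAM1 lists and 25 of 240 of SAM3 lists. In the settings chosen after, 17 of 105 values of SAM3 genes and 4 of 40 of SAM3 lists did so. The totals of settings fixed before include some that cannot change a ratio or a list mean, such as scaling between arrays and the variance model. Their shares are therefore lower than among the settings that can change a ratio.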

Other observations

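Genes measured on both arrays were compared after the results were seen. Of the 415 such genes, 47 had an unadjusted p under 0.05 on SAM1 and 26 on SAM3, with the dyes as labelled. Both held for 4 genes, where 2.9 are expected if the arrays were independent, and all 4 had the same sign on both arrays. With SAM3 replicate 3 exchanged these numbers were 24 genes on SAM3, 6 on both, 2.7 expected and 6 of the same sign, and with replicate 2 turned as well 62, 15, 7.0 and 14. Replicate 2 was turned because it ran opposite in these data, which by itself can raise the 62. Genes are not independent, the arrays would not be either if they share RNA, and no p is given. Of the 4 genes as labelled, trxh1, a thioredoxin h, was lower with -0.22 (SE 0.06) on SAM1 and -0.19 (SE 0.07) on SAM3. abcf1 was lower with -0.24 (SE 0.06) and -0.15 (SE 0.06). nfd106 was higher with 0.25 (SE 0.07) and 0.13 (SE 0.05), and a gene without a symbol here with 0.16 (SE 0.05) and 0.17 (SE 0.06). With the low and mid readings of SAM3 replicate 3 exchanged, trxh1 was -0.24, abcf1 -0.19, nfd106 0.008 and the gene without a symbol 0.16 on SAM3. With replicate 2 turned as well they were -0.32, -0.16, -0.06 and 0.15. None of these genes passed over all genes tested on either array.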
